A study of Homo sapiens and Mus musculus with 34 samples.

How the data were processed

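Methylation of cytosines was measured by bisulfite sequencing of a reduced, CpG-rich part of the genome in 18 libraries of human leukemia lines and 16 libraries of mouse hematopoietic progenitors. Per the labels, DNA was isolated with proteinase K, phenol-chloroform and ethanol, and libraries were made with the TruMethyl-Seq kit. The titles of the human libraries name the oxidative form of the assay, in which 5-hydroxymethylcytosine is read as unmethylated. The titles of the mouse libraries name the form without oxidation, in which 5-methylcytosine and 5-hydroxymethylcytosine are read together. Levels of the 2 species were therefore not compared with each other.

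The deposited tables give, for each cytosine position of a library, the percent methylation and the counts of methylated and unmethylated reads. Per the submitters' processing notes, bcl2fastq, Trim Galore and Bismark were used, without versions in the sources used here, and the builds were hg19 (GRCh37) and mm10 (GRCm38). The highest positions on chromosome 1 were 249239239 in the human tables and 195371271 in the mouse tables. The percent column as deposited is the methylated count over the sum of both counts, so tests used the counts. Whether duplicate reads were removed is not given in the sources used here. Reads without molecular identifiers are not independent molecules, so the intervals given here cover counting error only.

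Groups came from the titles and characteristics. Each human line had 3 libraries at each of 0, 12 and 72 h with vitamin C, and nothing in the labels pairs libraries across times. Mouse libraries carried a number, 39 or 46, at each of days 3, 7, 10 and 14 and in each doxycycline state. The design text names 2 mouse progenitor lines, so 39 and 46 were taken as line numbers and used as a block. Deviations from the group means of libraries with the same number correlated across tiles at 0.397 to 0.487 (median 0.435) over 28 pairs of groups. Nothing in the labels says that libraries of a group came from separate cultures. The p-values then measure only the spread between these libraries, which may be technical.

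Libraries of the same group were compared before averaging. Chi-square per degree of freedom over tiles was 2.01 to 2.23 between human libraries of one group and 4.41 to 5.09 between the 2 mouse libraries of one group, which are the 2 lines. No libraries agreed within sampling noise, and each was counted as 1 replicate.

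Positions on the autosomes and X with at least 10 reads in every library of a fit were kept. These were 437989 positions in HL60, 499956 in MOLM13, 258187 over all 18 human libraries and 194161 in mouse. Positions were summed into fixed windows of 1000 bp, called tiles, with at least 3 such positions. This gave 38886, 44446, 25814 and 17743 tiles, of which 36243, 42616, 24965 and 16511 were neither fully methylated nor fully unmethylated and were tested. The median number of reads per tile and library was 116, 123, 125 and 144.

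Global methylation was the unweighted mean over shared positions, 1 value per library. Human groups were compared with exact two-sided permutation tests of 3 libraries against 3, whose smallest possible p is 0.1, and with an exact one-way permutation test over the 3 times (1680 arrangements). Mouse libraries with and without doxycycline were compared with an exact two-sided sign-flip test on 8 pairs of the same line and day (256 sign patterns). Tiles were also classed by their mean over all libraries of the fit as under 20%, 20 to 80% or over 80%. Benjamini-Hochberg adjustment covered the 5 global comparisons as one family and the 15 class comparisons as another.

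Each tile was tested with a quasi-binomial logistic model of methylated and unmethylated reads in R 4.3.3 with the package data.table (version 1.17.8). The Pearson dispersion was squeezed across tiles with squeezeVar of limma 3.58.1, kept at 1 or above, and used in an F-test of the drop in deviance. A tile was called at a Benjamini-Hochberg adjusted p under 0.05. The human fits had time as a factor, with the 3 times sharing 1 estimate of the spread. The mouse fit had line as a block, day as a factor and doxycycline. A term for doxycycline by day and a term for line by time in the human libraries were tested in the same way. limma on log2((methylated + 0.5)/(unmethylated + 0.5)) and the quasi-likelihood test of edgeR 4.0.16 on both counts with a library effect were run as alternatives.

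The tests, groups, thresholds and alternatives were fixed before the data were examined, except where the closing section says otherwise. Alternatives covered the coverage minimum (5 and 20), the tile size (500 bp and single positions), the number of positions per tile, weighting by coverage, every position of each library, autosomes alone, removal of the top 1% of coverage, the floor of the dispersion, a minimum difference of 10 points, fits of 2 groups alone, the block, and leaving out each library. Tiles named in the text followed a fixed rule. For the 72 h and doxycycline comparisons these were up to 10 tiles of each direction with the largest difference among called tiles whose groups did not overlap, and for the 12 h and doxycycline-by-day comparisons up to 3. Where none was called, the 3 tiles with the smallest p were given as values. The rule did not cover the comparisons between lines or the line-by-time test, for which 3 tiles per direction or the 3 smallest p were taken by the same criteria after the values were seen.

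The model was tested on simulated counts with the real coverage, in which 200 tiles with a level of 20 to 80% were changed. In HL60 at 72 h, with 35063 to 35166 tiles tested, it recovered 0.5% of changes of 10 points, 25.5% of 20 points and 80.5% of 30 points. In MOLM13 at 72 h, with 41719 to 41742 tiles tested, the shares were 0, 39 and 85%. For doxycycline in mouse, with 15837 to 15916 tiles tested, they were 0.5, 75 and 98%. Tiles of other levels were not covered. At 20 points, 3 of 54 calls were false in HL60, 7 of 85 in MOLM13 and 3 of 153 in mouse. At 30 points the false calls were 11 of 172, 11 of 181 and 5 of 201.

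Reads of the other human line were measured at positions with no read in any of the 3 libraries of a line at 0 h and at least 10 reads in each 0 h library of the other line. There were 2609 such positions for HL60 and 2408 for MOLM13. The share was the part of a library's reads that lay there, divided by the mean of that part in the 72 h libraries of the other line, with exact 95% Poisson intervals. Checked on a 72 h library of each line mixed by computation with 5% of reads of the other line, the measure returned 5.23% for HL60 (0.404% before mixing) and 5.20% for MOLM13 (0.253% before mixing). The mixing drew counts at these positions, so it checks the scale of the measure and not where such reads come from. This measure was added after the data were seen.

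The gene table at hand gives a human assembly other than the build of the tables, so coordinates were not converted and no gene was assigned to a tile. The planned promoter tests and the fixed gene lists were not run for the same reason. Coordinates are 1-based as deposited, in hg19 for human and mm10 for mouse.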

Results

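DNA methylation was profiled in HL60, a human promyelocytic leukemia line, in MOLM13, a human acute myeloid leukemia line, and in mouse hematopoietic progenitors. The human lines were grown with vitamin C, a cofactor of the TET dioxygenases that oxidise 5-methylcytosine, for 0, 12 or 72 h, with 3 libraries per line and time. The mouse progenitors carried an shRNA against Tet2 that doxycycline turns off. Libraries of lines 39 and 46 were made with and without 1 ug/ml doxycycline at days 3, 7, 10 and 14, giving 16 in all. Reads summed over positions were 24925853 to 42048542 per library in HL60, 24979450 to 47481485 in MOLM13 and 12057954 to 19783423 in mouse. Median coverage per position was 6 to 10, 6 to 11 and 8 to 13 reads. At the positions used, which had 10 or more reads in every library of a set, mean coverage per library was 18.8 to 30.2, 19.9 to 35.3 and 21.4 to 33.8 reads. The labels name no culture grown for 12 or 72 h without vitamin C, so treatment and time in culture are 1 factor in the human comparisons.

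The first question was whether methylation of HL60 changed within 12 h of vitamin C. Mean methylation over shared positions was 23.01% ± 0.0967 (SD, n = 3) at 12 h and 22.84% ± 0.0312 (n = 3) at 0 h, a difference of 0.166 points (SE 0.0587). The 20312 tiles with a mean level under 20% were 0.375 points higher at 12 h (SE 0.0834), while the 9447 tiles over 80% differed by -0.244 points (SE 0.0199). The 9127 tiles of 20 to 80% differed by 0.0123 points (SE 0.0737), which turned to -0.153 points with coverage minimums of 5 and 20. Tiles over 80% were at -0.184 points (exact permutation p = 0.5) with a coverage minimum of 20 and -0.422 points with at least 1 position per tile. Mean methylation was higher on 18 of 22 autosomes and lower on 4, from -0.247 points on chromosome 18 to 0.363 on chromosome 10. At positions that MOLM13 but not HL60 had covered at 0 h, the 12 h libraries held reads at 5.80% (95% interval 5.58 to 6.03), 3.79% (3.59 to 4.00) and 3.09% (2.93 to 3.25) of their level in MOLM13, against 0.176 to 0.404% in the 72 h libraries.

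One tile of HL60 passed the test at 12 h. It spans 58514000 to 58514999 on chromosome 19 (hg19), with 32 positions from 58514010 to 58514338 and 520 to 1093 reads per library. Its methylation was 0 of 1828 reads summed over positions at 0 h, which allows a level of up to 0.164% if these were independent. It was 3.98% ± 0.436 (n = 3) at 12 h (quasi-binomial model with limma's squeezed dispersion, adjusted p = 0.00426) and 0.0537% at 72 h. In MOLM13 the same tile was methylated at 93.0% ± 1.75 (n = 3) at 0 h. From that level, the estimated share of MOLM13 reads alone predicts 3.93% in HL60 at 12 h. At an unadjusted p under 0.05 stood 2727 of the 36243 tiles, 1809 higher and 918 lower. limma called 7 tiles and edgeR 10, all higher, and the count was 0 without any one of the 0 h libraries 7, 8 or 9 or with a coverage minimum of 20. With a coverage minimum of 5 this tile did not pass (4.77 points, adjusted p = 0.559), although 7 others did. The global difference has an exact permutation p of 0.1, the smallest that 3 libraries against 3 can give (adjusted 0.125), and it turned to -0.446 points over every position of each library. It was 0.110 points without library 16 of 12 h and 0.0912 points (exact permutation p = 0.3) with a coverage minimum of 20. Over the positions shared by all 18 human libraries it was 0.0755 points as measured and -0.161 points with the share of MOLM13 reads taken out. Over the 25814 tiles of those positions it was 0.119 points, and -0.0406 points over the 15656 tiles on which the 2 lines were alike. Alike means under 5 points apart in the 72 h libraries. By the HL60 level in those libraries, 11368 of the alike tiles were under 20%, against 15515 of all tiles. The 2 sets thus differ in their mix of levels.

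In MOLM13 at 12 h mean methylation was 30.67% ± 0.0355 (n = 3), against 30.93% ± 0.0701 (n = 3) at 0 h, a difference of -0.259 points (SE 0.0454). The difference was -0.561 points (SE 0.0729) in the 16208 tiles over 80%, -0.610 points (SE 0.157) in the 10955 tiles of 20 to 80% and -0.0699 points (SE 0.0292) in the 17283 tiles under 20%. All 22 autosomes were lower, from -0.557 points on chromosome 3 to -0.215 on chromosome 2. At positions that HL60 but not MOLM13 had covered at 0 h, the 3 libraries held reads at 4.87% (95% interval 4.65 to 5.10), 3.65% (3.47 to 3.83) and 4.77% (4.57 to 4.97) of their level in HL60, against 0.212 to 0.265% at 72 h. The global difference and the 3 class differences each have an exact permutation p of 0.1, and the global difference turned to 0.237 points when positions were weighted by coverage. It was -0.132 points with a coverage minimum of 20. Over the positions shared by all 18 human libraries it was -0.329 points as measured and -0.0743 points (exact permutation p = 0.4) with the share of HL60 reads taken out. Over the tiles of those positions it was -0.464 points, and -0.0716 points over the tiles on which the 2 lines were alike, which were not matched to the others by level. The difference in tiles under 20% was -0.0136 points (exact permutation p = 0.7) with a coverage minimum of 20, -0.0436 points without library 1 of 0 h and 0.0551 points with at least 1 position per tile. With at least 1 position per tile, tiles of 20 to 80% differed by -0.217 points (exact permutation p = 0.3).

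No MOLM13 tile passed the quasi-binomial test at 12 h among 42616, where 3167 had an unadjusted p under 0.05 and 63.5% of these were lower. limma and edgeR also called 0, with 2637 and 2392 tiles at an unadjusted p under 0.05, and a coverage minimum of 5 gave 23 calls, 6 higher and 17 lower. The smallest p belonged to 100634000 to 100634999 on chromosome 13, at 0.0999% ± 0.0426 at 0 h and 0.885% ± 0.148 at 12 h (87 positions, 1517 to 3488 reads, limma-squeezed adjusted p = 0.229), and this tile passed with a coverage minimum of 5 (0.746 points, adjusted p = 0.0319). The tile at 131762000 to 131762999 on chromosome 10 stood at 17.4% ± 2.09 and 8.44% ± 0.744 (30 positions, 429 to 911 reads). The tile at 65548000 to 65548999 on chromosome 11 stood at 6.12% ± 1.38 and 2.32% ± 0.335 (43 positions, 570 to 1103 reads), each with n = 3.

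**Figure D1:**
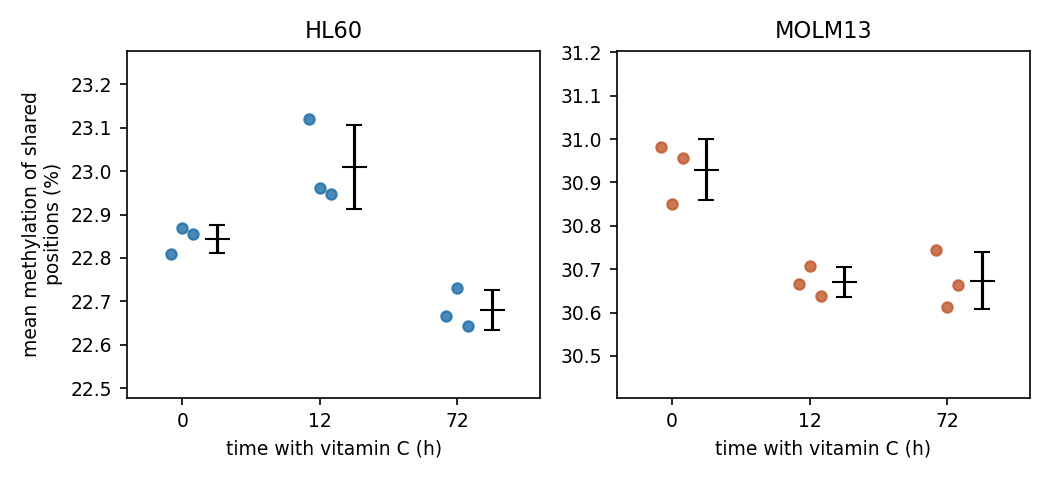
Mean methylation (%) over shared positions against time with vitamin C (h), with 1 point per library and bars for the mean and SD of 3 libraries; the left panel is HL60 and the right panel MOLM13, on axes that do not start at 0. All 3 HL60 libraries lie above the 0 h libraries at 12 h and below them at 72 h, and all MOLM13 libraries of 12 and 72 h lie below those of 0 h.

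**Figure D2:**
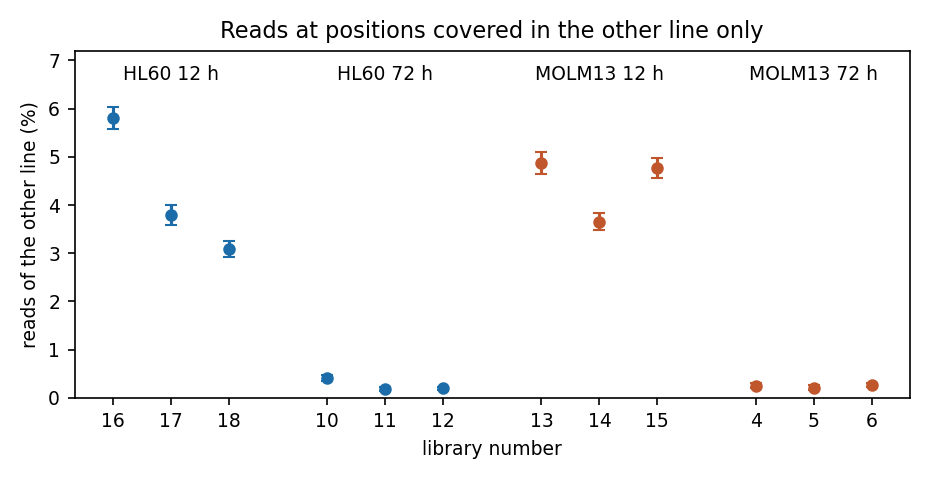
Reads of the other line (%) in each library of 12 and 72 h, measured at positions covered at 0 h in the other line only, with 95% Poisson intervals for counting error. The 6 libraries of 12 h lie between 3.09 and 5.80% and the 6 libraries of 72 h between 0.176 and 0.404%.

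After 72 h with vitamin C mean methylation of HL60 was 22.68% ± 0.0460 (n = 3), a difference of -0.164 points from 0 h (SE 0.0321). All 3 level classes were lower, by -0.106 points (SE 0.0167) in tiles under 20%, -0.447 points (SE 0.175) in tiles of 20 to 80% and -0.286 points (SE 0.0625) in tiles over 80%. All 22 autosomes were lower, from -0.387 points on chromosome 22 to -0.0256 on chromosome 21. The 72 h difference and each class difference have an exact permutation p of 0.1 (adjusted 0.125 and 0.136). Over the 3 times, the exact one-way permutation test gave p = 0.00357 for the global level and for tiles under 20%, 0.025 for tiles of 20 to 80% and 0.0214 for tiles over 80%. This test includes the 12 h libraries with their MOLM13 reads and does not show a change at 72 h by itself. Over the positions shared by all 18 human libraries its exact permutation p was 0.00357 for the global level as measured and 0.0179 with the other line's share taken out. Over every position of each library, shared or not, the 72 h difference was 0.849 points, weighted by coverage it was -0.118 points (exact permutation p = 0.9), and over tiles on which the 2 lines were alike it was -0.0853 points, against -0.192 over all tiles shared by the lines. For 72 h the alike tiles were chosen by the 12 h libraries, and they were not matched to the others by level. With a coverage minimum of 20, tiles under 20% differed by -0.0229 points (exact permutation p = 0.3) and the 331 tiles over 80% by -0.0403 points (p = 0.8).

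No HL60 tile passed at 72 h by the quasi-binomial test, limma or edgeR among 36243, with 2254, 1816 and 1543 at an unadjusted p under 0.05. The 2254 were 6.22% of the tiles tested, against 5.69 to 5.76% of unchanged tiles in the simulation. Of the 2254 tiles, 60.9% were lower. The smallest p was found at 10720000 to 10720999 on chromosome 6, with 30.8% ± 6.50 at 0 h and 61.3% ± 6.86 at 72 h (6 positions, 66 to 114 reads, limma-squeezed adjusted p = 0.773). Its difference turned to -2.66 points with a coverage minimum of 5. The tile at 174451000 to 174451999 on chromosome 4 was at 29.6% ± 3.36 and 8.73% ± 0.348 (6 positions, 66 to 168 reads). The tile at 39624000 to 39624999 on chromosome 19 was at 22.01% ± 2.69 and 5.61% ± 1.33 (4 positions, 57 to 102 reads), each with n = 3.

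MOLM13 at 72 h had a mean methylation of 30.67% ± 0.0661 (n = 3), which differed from 0 h by -0.256 points (SE 0.0556). Tiles under 20% differed by -0.199 points (SE 0.0304), tiles of 20 to 80% by -0.537 points (SE 0.185) and tiles over 80% by -0.3996 points (SE 0.0485). As in HL60, all 22 autosomes were lower, here from -0.541 points on chromosome 18 to -0.0998 on chromosome 4. These differences have an exact permutation p of 0.1. The exact one-way permutation test over the 3 times gave p = 0.0357 for the global level, 0.00357 for tiles under 20%, 0.025 for tiles of 20 to 80% and 0.0107 for tiles over 80%. As in HL60 it includes the 12 h libraries. Over the positions shared by all 18 human libraries its exact permutation p was 0.00714 for the global level as measured and 0.0143 with the other line's share taken out. The 72 h difference was -0.750 points (exact permutation p = 0.4) weighted by coverage and -0.749 points (p = 0.7) over every position of each library. It was -0.146 points over tiles on which the 2 lines were alike, not matched by level, against -0.308 over all tiles shared by the lines. Tiles under 20% differed by -0.0980 points with a coverage minimum of 20.

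No MOLM13 tile passed at 72 h by the quasi-binomial test, limma or edgeR, with 2831, 2391 and 2063 tiles at an unadjusted p under 0.05. The 2831 were 6.64% of the tiles tested, against 5.71 to 5.79% of unchanged tiles in the simulation. Of the 2831 tiles, 66.5% were lower. The 3 tiles with the smallest p were all lower at 72 h. The tile at 560000 to 560999 on chromosome 19 was at 49.7% ± 3.84 at 0 h and 31.1% ± 2.92 at 72 h (7 positions, 168 to 415 reads, limma-squeezed adjusted p = 0.414). The tile at 85577000 to 85577999 on chromosome 16 was at 74.8% ± 1.86 and 48.4% ± 10.8 (8 positions, 103 to 180 reads). The tile at 16181000 to 16181999 on chromosome 19 was at 65.7% ± 2.03 and 50.4% ± 4.29 (10 positions, 211 to 379 reads), each with n = 3.

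**Figure D3:**
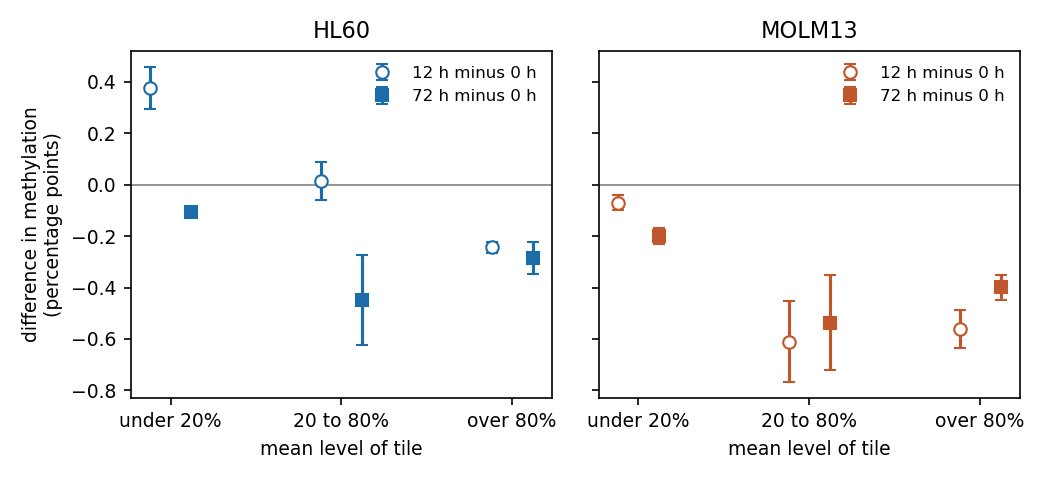
Difference in methylation from 0 h (percentage points) for tiles under 20%, 20 to 80% and over 80%, in HL60 on the left and MOLM13 on the right; open circles are 12 h, filled squares 72 h, and bars are 1 SE of the difference with 3 libraries per group. Each class is lower at 72 h in both lines, and tiles under 20% of HL60 are 0.375 points higher at 12 h.

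Whether the lines responded differently was tested over the 258187 positions shared by all 18 human libraries. The plan listed this test for tiles at 72 h, but not the tests of the global level and level classes. At 72 h the global change was -0.166 points in HL60 and -0.238 points in MOLM13, a difference of 0.0716 points (exact permutation of times within lines, 400 arrangements, p = 0.61). At 12 h the change was 0.0755 points in HL60 and -0.329 points in MOLM13, a difference of 0.405 points (exact permutation p = 0.005, adjusted 0.0133). That difference was 0.217 points in tiles under 20% and 1.71 points in tiles of 20 to 80%, each with an exact permutation p of 0.005, and 0.113 points in tiles over 80% (p = 0.415). With the share of the other line's reads taken out of each library, the 12 h difference was -0.0865 points (exact permutation p = 0.3).

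No tile differed between the lines in its 72 h change by the quasi-binomial test, limma or edgeR among 24965, with 1358, 1252 and 1007 at an unadjusted p under 0.05. The smallest p were at 2634000 to 2634999 on chromosome 19, where HL60 was at 10.0% at 0 h and 0% at 72 h and MOLM13 at 20.2% and 22.2%, and at 135352000 to 135352999 on chromosome 9, where HL60 was at 71.1% and 59.2% and MOLM13 at 20.9% and 42.1%. The next was at 19568000 to 19568999 on chromosome 19, with 85.0% and 89.3% in HL60 and 98.9% and 91.4% in MOLM13. These tiles hold 3 positions each with 36 to 141 reads per library (limma-squeezed adjusted p = 0.872).

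Before treatment the 2 human lines differed from each other over much of the measured genome. Mean methylation over 25814 tiles was 30.2% in HL60 and 37.8% in MOLM13 at 0 h, and HL60 was lower on all 22 autosomes, from -10.1 points on chromosome 10 to -3.62 on chromosome 18. The quasi-binomial test called 9559 of 24965 tiles. Of these, 1816 were higher in HL60 with a median difference of 15.6 points, and 7743 were lower with a median of -22.7 points. limma called 9029 and edgeR 9011, and the count was 289 with a coverage minimum of 20, 30454 with a minimum of 5 and 47244 for single positions.

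Tiles higher in HL60 included 23032000 to 23032999 on chromosome 20, at 93.5% ± 5.68 in HL60 and 0.203% ± 0.352 in MOLM13 (4 positions, 64 to 224 reads). They also included 17246000 to 17246999 on chromosome 19, at 91.7% ± 1.81 and 0.0813% ± 0.141 (6 positions, 71 to 410 reads), and 77127000 to 77127999 on chromosome 10, at 94.7% ± 1.15 and 3.36% ± 0.369 (4 positions, 48 to 130 reads). Among tiles lower in HL60, 62138000 to 62138999 on chromosome 11 was at 0.230% ± 0.398 in HL60 and 98.0% ± 0.801 in MOLM13 (5 positions, 60 to 184 reads). The tile at 39612000 to 39612999 on chromosome 13 was at 0 of 263 summed reads in HL60 and 97.4% ± 2.48 in MOLM13 (3 positions, 37 to 107 reads). The 0 allows up to 1.14% if the summed reads were independent. The tile at 11431000 to 11431999 on chromosome 4 was at 0.855% ± 0.741 and 98.0% ± 2.42 (4 positions, 48 to 140 reads). Each level has n = 3, and the limma-squeezed adjusted p of these 6 tiles ranged from 4.33e-13 to 3.88e-10.

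In the mouse progenitors the question was whether restoring Tet2, by turning off its shRNA with doxycycline, changed methylation. Mean methylation over 194161 shared positions was 17.008% ± 0.132 (SD, n = 8) with doxycycline and 17.002% ± 0.141 (n = 8) without, a difference within pairs of 0.00655 points (SE 0.0121) that was positive in 4 of 8 pairs. The 13804 tiles under 20% differed by 0.00162 points (SE 0.0120), the 1553 tiles of 20 to 80% by 0.0229 points (SE 0.0810) and the 2386 tiles over 80% by -0.0297 points (SE 0.0400), each positive in 4 of 8 pairs. Of 19 autosomes 11 were higher and 8 lower, from -0.152 points on chromosome 14 to 0.0602 on chromosome 3. The exact sign-flip permutation p was 0.586 for the global level and 0.883, 0.781 and 0.484 for the classes. Weighted by coverage, the global difference was -0.216 points (SE 0.0827), lower with doxycycline in 7 of 8 pairs, with an exact sign-flip permutation p of 0.0156. Without the pair of day 7 in line 39, which was at -0.735 points, it was -0.142 points (SE 0.0423, exact sign-flip permutation p = 0.0313). Unweighted, that pair was at -0.00804 points over the same positions. The weights are each library's own coverage, so the weighted mean also moves with how reads are spread over positions. Whether levels or the spread of reads moved it was not tested. The 8 pairs are days of the same lines, and nothing in the labels says that days of a line were independent cultures. The SEs and sign-flip tests given here treat the pairs as independent. They describe these libraries and no wider group of lines.

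No mouse tile passed for doxycycline by the quasi-binomial test, limma or edgeR among 16511, with 1088, 767 and 593 at an unadjusted p under 0.05. The 1088 were 6.59% of the tiles tested, and 28 of 100 splits of the same libraries, the real one included, gave as many. The tile at 17097000 to 17097999 on chromosome 1 (mm10) had the smallest p, at 3.91% ± 1.57 with and 1.83% ± 0.644 without doxycycline and higher in 8 of 8 pairs (23 positions, 385 to 818 reads, limma-squeezed adjusted p = 0.735). The tile at 171503000 to 171503999 on chromosome 1 was at 0.180% ± 0.509 and 1.78% ± 3.14, higher in 0 of 8 pairs (12 positions, 167 to 350 reads). The tile at 47695000 to 47695999 on chromosome 17 was at 1.04% ± 0.828 and 0.174% ± 0.152, higher in 8 of 8 pairs (29 positions, 518 to 841 reads), each with n = 8. Without the lower limit of 1 on the dispersion the count was 2829 tiles, 1410 higher and 1419 lower.

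The doxycycline difference was also tested for a trend over days 3 to 14. No tile passed by the quasi-binomial test, limma or edgeR, with 1107, 808 and 607 tiles at an unadjusted p under 0.05. The smallest p were at 98726000 to 98726999 on chromosome 4, with a slope of -3.13 points per day (4 positions, 40 to 171 reads), at 24080000 to 24080999 on chromosome 11, with -0.461 points per day (6 positions, 90 to 228 reads), and at 36473000 to 36473999 on chromosome 8, with 3.39 points per day (4 positions, 59 to 114 reads; limma-squeezed adjusted p = 0.716). Tested day by day, 0 tiles passed on days 3, 7, 10 and 14 by the quasi-binomial test. At an unadjusted p under 0.05 were 662, 664, 716 and 692 tiles, or 4.01 to 4.34% of those tested. The other tools were not run per day. Without the limit on the dispersion 852 tiles passed for the trend.

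**Figure D4:**
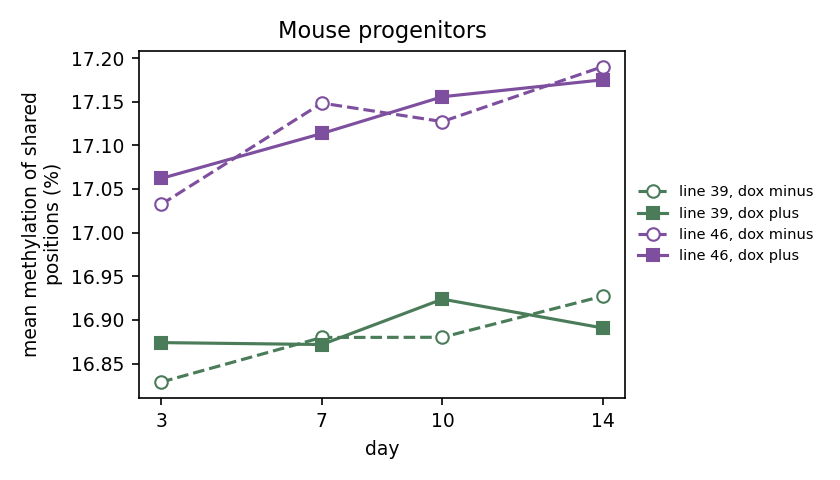
Mean methylation (%) over shared positions of each mouse library against day of culture, with green for line 39, purple for line 46, filled squares with and open circles without doxycycline; the axis does not start at 0. Line 46 lies above line 39 at each day and doxycycline state, while the 2 doxycycline states cross.

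The 2 mouse lines differed from each other. The plan listed the tile test between lines, but not the tests of level. Line 46 had a mean methylation of 17.13% ± 0.0547 (n = 8) and line 39 of 16.88% ± 0.0313 (n = 8), a difference of 0.241 points (SE 0.0115) with line 46 higher in 8 of 8 pairs of the same day and doxycycline state (exact sign-flip permutation p = 0.0078). Line 46 was higher by 0.154 points (SE 0.0131) in tiles under 20%, by 1.27 points (SE 0.0677) in tiles of 20 to 80% and by 0.167 points (SE 0.0553) in tiles over 80%, in 8, 8 and 7 of 8 pairs (exact permutation p = 0.0078, 0.0078 and 0.0234). All 19 autosomes were higher in line 46, from 0.0200 points on chromosome 9 to 0.755 on chromosome 7. Mitochondrial methylation, taken as a gauge of incomplete conversion without a test of it, was also higher in line 46, at 2.56% ± 0.655 against 0.949% ± 0.124 (n = 8 each). The share of reads at mitochondrial positions was lower in line 46, at 0.127% ± 0.0165 against 0.151% ± 0.0131. The quasi-binomial test called 1351 of 16511 tiles, 799 higher in line 46 with a median of 7.79 points and 552 lower with a median of -8.99 points, and limma called 1192 and edgeR 1095. The count was 57 with a coverage minimum of 20, 3199 with 5, 2531 with at least 1 position per tile, 4547 for single positions, 4778 without the lower limit on the dispersion and 558 with a difference of at least 10 points. Libraries of 1 line are days and doxycycline states of that line, so these tests describe the 2 lines and no wider group.

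Tiles higher in line 46 included 5384000 to 5384999 on chromosome 6, at 67.1% ± 8.81 in line 46 and 1.33% ± 1.29 in line 39 (3 positions, 42 to 147 reads). Others were 105762000 to 105762999 on chromosome 7, at 71.1% ± 8.54 and 16.1% ± 5.6 (11 positions, 145 to 334 reads), and 118489000 to 118489999 on chromosome 5, at 80.04% ± 7.74 and 26.0% ± 5.09 (3 positions, 45 to 104 reads). Among tiles lower in line 46, 65309000 to 65309999 on chromosome 13 was at 11.8% ± 3.63 and 78.5% ± 5.91 (3 positions, 43 to 509 reads). The tile at 45742000 to 45742999 on chromosome 7 was at 36.6% ± 11.1 and 91.2% ± 4.40 (4 positions, 40 to 150 reads). The tile at 96264000 to 96264999 on chromosome 11 was at 8.79% ± 5.13 and 62.6% ± 11.9 (4 positions, 63 to 135 reads). Each level has n = 8, and the limma-squeezed adjusted p ranged from 1.97e-06 to 8.94e-05.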

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

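In this part the tests of explanations were chosen only after the result was seen, except for the test of conversion on the mouse tiles higher in line 46 and the test of a sequence variant on all mouse tiles called between lines.

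As measured, the change at 12 h differed between the human lines, by 0.405 points for the global mean, 0.217 points for tiles under 20% and 1.71 points for tiles of 20 to 80% (HL60 minus MOLM13). With the other line's share taken out, the global difference was -0.0865 points (exact permutation p = 0.3). The 12 h libraries drew attention for a second reason, as the estimated share of the other line's reads in them was on average 4.23% ± 1.41 (HL60, n = 3) and 4.43% ± 0.675 (MOLM13, n = 3), from positions that only the other line had covered at 0 h. Less complete conversion at 12 h is argued against, since it would raise HL60 tiles under 20% by 0.277 points also where the lines are alike, and the 11368 such tiles changed by -0.00188 points (SE 0.00980). Reads of the other line may account for the higher HL60 level and for the difference between lines at 12 h. With that share taken out, HL60 was not higher (-0.161 points) and the difference between lines was -0.0865 points. The lowest share among the 6 libraries of 12 h was 3.09%, against a highest of 0.404% at 72 h. Tiles moved towards the other line by 3.30% of the difference between lines in HL60 and 4.996% in MOLM13. The called tile on chromosome 19 stood at 3.98% where the share of the other line's reads predicts 3.93%. An effect of vitamin C or of 12 h in culture stays open and cannot be told apart from these reads by the 12 h libraries alone, because on tiles where the lines differ by under 5 points the change was -0.0406 points in HL60 (exact permutation p = 0.3, n = 3 each) and -0.0716 points in MOLM13 (p = 0.1, the smallest possible, libraries -0.0981 to -0.0543), against 0.119 and -0.464 over all shared tiles, and with the other line's share taken out it was -0.161 points in HL60 (p = 0.1, 0.0755 as measured) and -0.0743 points in MOLM13 (p = 0.4, -0.329 as measured). The alike tiles were not matched to the others by level. How such reads entered the libraries, before or after sequencing, was not tested. The titles number the 12 h libraries 13 to 18 and the other human libraries 1 to 12. Whether the 12 h libraries form a separate set of preparation or sequencing was not tested.

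Methylation at 72 h was lower in all 3 level classes and on all 22 autosomes of both lines. More complete conversion is argued against, since it allows tiles over 80% a change of -0.0103 points in HL60 and -0.0162 points in MOLM13, and these tiles differed by -0.286 points (SE 0.0625) and -0.3996 points (SE 0.0485), whereas with a coverage minimum of 20 the 331 HL60 tiles over 80% differed by -0.0403 points (SE 0.163), too uncertain to decide, and the 1056 MOLM13 tiles by -0.361 points (SE 0.0902). In tiles of 20 to 80% a loss of methylated cytosines in proportion to their level, as harsher conversion could give, cannot be told apart from the other explanations. These tiles differed beyond that proportion by -0.278 points (SE 0.179) in HL60 and -0.298 points (SE 0.187) in MOLM13, under 2 standard errors in each. Such a loss alone is argued against for tiles under 20%, at 2.81% and 2.44% at 0 h against 90.6% and 92.1% in tiles over 80%. They differed by -0.106 points (SE 0.0167) and -0.199 points (SE 0.0304), far beyond that proportion. With a coverage minimum of 20 HL60 was at -0.0229 points (SE 0.0110), too uncertain to decide. Vitamin C and 72 h of culture cannot be told apart, as there are 0 libraries of untreated cells at 72 h. More complete conversion acting together with a loss in proportion to level was not tested. Differences between the libraries of 0 and 72 h in the oxidation step or in preparation were not tested either. The fall is thus a hypothesis of an effect of vitamin C or of time in culture, with these technical explanations still open.

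The 1351 tiles that differed between mouse lines 39 and 46 were weighed as the third pattern. Less complete conversion in line 46 is argued against, since it cannot give the 552 tiles that were lower in line 46, and the tiles that were higher in it differed by a median of 7.79 points (lower quartile 3.75), above the 1.61 points by which mitochondrial methylation differed between the lines, and tiles of 20 to 80% and over 80% were higher on average by 1.27 points (SE 0.0677) and 0.167 points (SE 0.0553) where the rise of tiles under 20% allows 0.0752 and 0.0154. For the mean rise of 0.154 points in tiles under 20% such conversion cannot be told apart from methylation, as mitochondrial methylation rose with it. How far mitochondrial methylation measures conversion was not tested, so the 1.61 points are a bound only if it does. A sequence variant at 1 position of each tile is argued against for the 414 tiles that were called again after their most different position was left out, and for the remaining called tiles it cannot be told apart from a difference in methylation: 80.4% of all called tiles kept at least 0.5 of their difference without that position, but 30.6% stayed called, and the bound set beforehand asked for most of them. Only 1 position was left out per tile, so a variant that alters more than 1 position is not covered. A difference between the lines themselves, in origin or in the time since they were set up, is a biological explanation that stays open and untested.

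Reads at mitochondrial positions, which the comparisons of levels and tiles left out, took a larger share of all reads than in any 0 h library in 3 groups. In HL60 they made up 0.0691% ± 0.00328 at 12 h and 0.0468% ± 0.00709 at 72 h (n = 3 each), against 0.0387% ± 0.000556 at 0 h. In MOLM13 they made up 0.0583% ± 0.00664 at 12 h (n = 3), against 0.0403% ± 0.0104 at 0 h. Mitochondrial methylation was 3.13% at 12 h and 4.84% at 0 h in HL60, and 3.35% at 12 h and 5.57% at 0 h in MOLM13. Whether it follows conversion or the share of reads was not tested, so these differences were not used as a measure of conversion.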

How the results depend on the processing

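The tests on tiles where the 2 human lines differ by under 5 points, with the other line's share taken out, over positions shared by all 18 human libraries, without the 12 h libraries, and without 1 pair of the coverage-weighted doxycycline test were chosen only after the result was seen. Counts of 0 called tiles at 72 h in both lines and for the line-by-time test held under every alternative run, as did the direction of the MOLM13 global change at 72 h (-0.750 to -0.146 points). The cause was not tested for any change given here, except that stricter or looser coverage and position limits change the number of tiles tested.

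Global differences turned as follows. Over every position of each library they were -0.446 points for HL60 at 12 h, 0.849 points for HL60 at 72 h and -0.479 points for doxycycline. Weighted by coverage they were 0.237 points for MOLM13 at 12 h and -0.216 points for doxycycline, while HL60 at 72 h kept its direction at -0.118 points (exact permutation p = 0.9). The weighted mean also moves with how each library's reads are spread over positions. On positions shared by all 18 human libraries, HL60 at 12 h was at 0.0755 points as measured and -0.161 with the other line's share taken out, and over the tiles of these positions at 0.119, and -0.0406 where the lines are alike. MOLM13 at 12 h kept its direction there, at -0.329, -0.0743, -0.464 and -0.0716 in the same order. It was -0.132 with a coverage minimum of 20, -0.422 with 5 and -0.627 over every position. At 72 h the alike tiles were at -0.0853 in HL60 (all tiles -0.192) and -0.146 in MOLM13 (all tiles -0.308). Alike tiles were not matched to all tiles by level. HL60 at 12 h was at 0.0912 with a coverage minimum of 20 and 0.110 without library 16. For doxycycline it was -0.00272 points with a coverage minimum of 5 and -0.0431 points with 20.

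The count of HL60 tiles called at 12 h was 7 with a coverage minimum of 5 (without the reported tile, 4.77 points, adjusted p = 0.559), 0 with 20, 5 with at least 1 position per tile, 0 for single positions, 3 without the floor on the dispersion, 5 with only 2 groups in the fit, 0 with a difference of at least 10 points, 7 by limma and 10 by edgeR. Leaving out 1 library gave 0 to 2, with 0 without library 7, 8 or 9 of 0 h and 2 without library 17 or 18 of 12 h. MOLM13 at 12 h gave 23 with a coverage minimum of 5, the tile on chromosome 13 among them (0.746 points). HL60 against MOLM13 at 0 h gave 30454 with a coverage minimum of 5, 289 with 20, 17046 with at least 1 position and 47244 single positions (8697 to 9066 without 1 library). Without the floor, doxycycline gave 2829 and doxycycline by day 852. The mouse lines gave 3199 with a coverage minimum of 5, 57 with 20, 2531 with at least 1 position, 4547 single positions, 4778 without the floor and 558 with a difference of at least 10 points (1059 to 1145 without 1 library).

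Among level classes, HL60 tiles of 20 to 80% at 12 h turned to -0.153 points with coverage minimums of 5 and 20 and -0.313 with at least 1 position, and ranged from -0.0367 to 0.0730 without 1 library, being negative without library 7 of 0 h or 16 of 12 h. MOLM13 tiles under 20% at 12 h turned to 0.0551 with at least 1 position, and were at -0.0136 with a coverage minimum of 20 and -0.0436 without library 1 of 0 h. For doxycycline, tiles of 20 to 80% gave -0.0673, -0.372 and -0.0282 with a coverage minimum of 5, of 20 and at least 1 position, and -0.0362 to 0.0719 without 1 library; tiles over 80% gave 0.1198 with a minimum of 20, 0.0517 with at least 1 position and -0.0557 to 0.0138 without 1 library; tiles under 20% gave -0.00372 to 0.00834 without 1 library, -0.00596 without line 39, 0.0132 without line 46 and 0.0305 with a coverage minimum of 20. HL60 tiles at 72 h with a coverage minimum of 20 were at -0.0229 under 20% and -0.0403 over 80%. The HL60 tile on chromosome 6 turned to -2.66 points at 72 h with a coverage minimum of 5.

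Without the replicate block the doxycycline difference is 0.00655 points by construction, since both states hold the same lines and days. The exact permutation test without pairing by line or day gave p = 0.913. In the tile fits without the block, 0 tiles were called for doxycycline and 0 for doxycycline by day, and no call changed. The promoter and gene list alternatives were not run, for want of an annotation of the build used. In counts simulated at the depth and number of the human libraries, changes of 10 points were recovered in 0.5% of HL60 tiles and 0% of MOLM13 tiles.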

Other observations

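In this part the tests of concordance between the human lines and of a trend over days in mouse were chosen only after the result was seen, and the counts over other splits were planned.

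The level classes show where HL60 and MOLM13 differ at 0 h. Of 25814 tiles, 12650 were under 20% in both lines and 4697 over 80% in both. A further 484 tiles were under 20% in HL60 and over 80% in MOLM13, and 24 the reverse. The largest mixed class, 2332 tiles, was under 20% in HL60 and 20 to 80% in MOLM13. The lines lay within 5 points of each other in 59.8% of tiles, and the median absolute difference was 2.50 points, while 1449 tiles were higher in MOLM13 by over 50 points and 85 higher in HL60 by as much.

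No test was run of whether differences between the lines are spread evenly along chromosomes, so the windows here are a description. Over 736 windows of 1 Mb, 39.2% of tested tiles were called. In the window at 118000000 to 118999999 on chromosome 10 (hg19) 15 of 17 tiles were called, with a mean difference of -31.7 points (HL60 minus MOLM13), and in the next window 10 of 13 were called, 0 of them higher in HL60. At 223000000 to 223999999 on chromosome 2, 8 of 10 tiles were called, all lower in HL60, with a mean difference of -40.5 points. At 54000000 to 54999999 on chromosome 12, 24 of 32 tiles were called, 19 of them lower in HL60. Between the mouse lines, 8.59% of tested tiles were called over 597 windows, against 6 of 11, all higher in line 46, at 20000000 to 20999999 on chromosome 12 (mm10). These windows were picked after their values were seen, and neighbouring tiles are not independent.

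A hypothesis was that the same tiles changed in both human lines by 72 h. Across 25814 tiles the 72 h changes of HL60 and MOLM13 correlated at 0.0147, and exchanging the 0 h and 72 h labels within lines gave as high a value in few of 400 arrangements (exact one-sided permutation p = 0.03, two-sided 0.06), with a highest of 0.0197 among the arrangements. A correlation of this size may reflect a small change shared by both lines, but it is close to 0 and tiles are not independent replicates. At 12 h the correlation was -0.0490, the lowest of the 400 arrangements (exact two-sided permutation p = 0.01), the direction that reads of the other line in each library would give.

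Another hypothesis was that mouse methylation rises with days in culture. The mean slope was 0.00859 points per day (SE 0.00220) and was positive in 4 of 4 series of line and doxycycline state. The 4 series share their days, so the days were exchanged in all series together, which gave an exact one-sided permutation p of 0.0417, the smallest that 24 arrangements allow (2-sided 0.0833). Weighted by coverage, the mean slope was -0.00451 points per day (SE 0.00703), negative in 3 of 4 series (exact one-sided permutation p = 0.583). Whether methylation rises with days is thus left open, and depth and library preparation by day were not separated from time.

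Other splits of the same libraries were counted for each fit across tiles. With 3 libraries against 3 the 10 splits are too few for a share under 0.05. The called count was the highest in 1 of 10 splits for HL60 at 12 h (1 tile, highest other 0) and for the lines at 0 h (9559, highest other 0), while for the 0 tiles of HL60 at 72 h, MOLM13 at 12 h and MOLM13 at 72 h the comparison decides nothing, since 10 of 10 splits must give as many (highest other 1 in each). For tiles at an unadjusted p under 0.05 the real split ranked highest, 1 of 10, in HL60 at 12 h (2727, highest other 2317), HL60 at 72 h (2254, highest other 2186), MOLM13 at 12 h (3167, highest other 2587), MOLM13 at 72 h (2831, highest other 2643) and the lines at 0 h (10997, highest other 2429). Over 100 drawn splits chance cannot be excluded for the line-by-time count at an unadjusted p under 0.05 (1358, as large in 31, highest other 1482), for doxycycline (1088, as large in 28, highest other 1148) or for doxycycline by day (1107, as large in 28, highest other 1172). For their 0 called tiles the comparison decides nothing, since 100 of 100 splits must give as many (highest other 1, 0 and 0). For the mouse lines 1 of 100 splits, the real one, gave as many called tiles (1351, highest other 1) and as many at an unadjusted p under 0.05 (3520, highest other 2279). This shows only that libraries of the same number resemble each other. The other splits leave the line difference in the spread, and each line is 1 unit, so chance is not excluded.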
